A study of Mus musculus with 6 samples.

How the data were processed

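RNA was measured by sequencing in 6 libraries of immature mouse chondrocytes. Each of the 2 genotypes, wildtype and Ezh2-deficient, gave 1 library at each of days 3, 7 and 14 of micromass culture. The deposited table held, for each library, a read count per gene and an RPKM value per gene. The counts were whole numbers as deposited, not normalized. Every count in every library was even, as if each sequenced fragment added 2 reads, which the sources used here do not state. A fragment is taken below as 2 counts. The RPKM values were made by the authors from the same counts, scaled by a coding length and by a total per library, as the file headers and the values themselves show. The counts in the table summed to between 80.2% and 82.8% of the totals behind the RPKM values. CASAVA 1.9, TopHat 12.0.6 and HTSeq (without a version) and the mouse build mm10 were named in the submitters' processing notes, with no role or order. Strandedness of the libraries, the gene annotation used for counting and any upstream filter were not given in the sources used here. Reads from overlapping and antisense genes could therefore not be told apart, and reads of near-identical copies (Bglap and its neighbours, ribosomal protein genes and Gapdh with their pseudogenes) could have been split between them.

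The table held 23358 entries with 23315 distinct gene symbols, of which 69 entries shared a symbol with another, and 3717 entries had 0 counts in all 6 libraries. Some symbols were older names (Emr1, Sc4mol, Accn1, Lect1). Coordinates are those of the deposited table. Of its symbols, 20924 were also in a GENCODE annotation of the mm10 build, and 99.52% of these (20824) overlapped the annotated gene on the same chromosome. Columns without a sample numbered 0. All columns were matched to libraries by title.

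Depth ran from 51985214 to 79323302 counts per library. Levels are given as counts per 1000000 counts of the library (CPM). A floor of 3 fragments corresponded to between 0.0763 and 0.114 CPM. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. All analysis used the counts. The RPKM values were not used in any test. CPM was computed from counts with library sizes scaled by the trimmed mean of M values (TMM), whose factors lay between 0.935 and 1.09.

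Tests were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr with a minimum count of 10 and day as the group, which left 16280. The main test was edgeR's quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The genotype difference was fitted with day as a factor, so that the 3 days stood in for replicates, with 2 residual degrees of freedom. Differences between days came from the same model, with the 2 genotypes standing in for replicates. Another fit added the product of genotype and centred log2 day, which left 1 residual degree of freedom, and asked whether the genotype difference changed per doubling of day. A full interaction of genotype with day left none and was not tested. Standard errors (SE) of log2 fold changes were computed as the absolute log2 fold change divided by the square root of F. Within a single day each genotype had 1 library, so no test was made. Genes were counted there by a fixed rule, namely at least 1 CPM in the higher library, at least 2-fold apart with a prior count of 2, and an exact 95% counting interval of the ratio that excluded 1.

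Of 36 gene lists for pathways and cell types, 35 had at least 3 tested members. Lists were tested with camera (limma) at a preset correlation between genes of 0.01, with camera at an estimated correlation and with fry. Each was Benjamini-Hochberg adjusted over the lists. At an estimated correlation camera uses only the residual degrees of freedom of the fit, 2 or 1. Few lists can then pass, whatever their correlation. The fry test asks whether the genes of a list move on balance in 1 direction, without comparison with other genes. The designs, the lists, the rule for naming genes and all alternatives except 2 were fixed before the data were examined. By that rule Ezh2 came first. For the genotype difference and for day 14 against day 3, the 12 largest changes in each direction were taken among genes that passed, had a mean of at least 1 CPM and had the same sign on every day or in both genotypes. Where none passed in a direction, the 6 genes with the smallest p were taken and are said not to pass. For the other day comparisons and the trend with day the 5 largest in each direction were taken, and for single days the 3 largest with at least 5 CPM. Predicted and uncharacterised symbols were left out. Up to 4 members of each list with the smallest p, members of lists that passed and a fixed set of cartilage, bone and Polycomb genes were added.

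Alternatives for normalization and filtering were RLE factors, total counts only, upper-quartile factors, no filter and a filter of 1 CPM in 3 libraries. Alternatives for the test were DESeq2, limma-voom, robust dispersion, leaving out each library or each day's pair, no day term, log2 day as a linear term, no genotype term, day on a linear scale, sex-linked genes left out, and other thresholds for the single days. The 2 chosen after seeing the data were halved counts and leaving out the ribosomal RNA gene Rn45s.

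The models were tested on simulated counts for the 16280 genes of which 67 were changed by 0.5, 67 by 1 and 66 by 2 on the log2 scale. With the spread of each gene taken from the libraries, edgeR recovered 20, 66 and 66 of these for the genotype difference, and 38 of 190 calls (20%) were false. A second scenario, with the spread following the trend over expression, was added after these false calls were seen. There edgeR recovered 23, 64 and 66, and 7 of 160 calls (4.38%) were false. The false share was 21.1% and 5.45% for DESeq2, and 24.1% and 3.8% for limma-voom. In the first scenario edgeR, DESeq2 and limma-voom were close, with 190, 199 and 203 calls. In the real libraries they were far apart, with 2, 607 and 40. Genes were simulated independently, and no simulated genotype difference varied with day in that test. The recovery therefore does not show how many real changes edgeR could find. For day 14 against day 3 edgeR recovered 3, 54 and 66 in the first scenario (15.8% false) and 6, 64 and 66 in the second (1.45% false). For the trend with day it recovered 47, 67 and 66 (20% false) and 42, 67 and 66 (4.89% false). A simulated list of 29 genes shifted by 0.5 was found by camera in each scenario, with 0 other lists called. These genes were drawn independently, whereas in the libraries the estimated correlation reached 0.98 for the cell cycle list. The 0 other lists therefore say nothing of false calls among genes that move together. Nothing in the labels says that the libraries came from separate cultures, animals or litters. P-values therefore measure only the spread between these samples, which may be technical. In the genotype and day fits that spread is how far the genotype difference varies from day to day, which may also be real. Genes whose difference changes with day are thus less likely to pass.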

Results

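Chondrocytes of the knee and hip (tibial plateau, femoral condyles and femoral head) were taken from mice at post-natal day 5 and grown as micromasses, dense drops of cells that lay down cartilage matrix. The medium held insulin, transferrin and selenium, ascorbic acid and β-glycerol phosphate, a phosphate source used for mineralising cultures. The series compared wildtype cells with cells deficient in Ezh2, the enzyme of Polycomb repressive complex 2 that methylates histone H3 at lysine 27. The micromasses were cultured for 3, 7 or 14 days, and each genotype gave 1 library per day, 6 in all. Total counts were 70489216 (wildtype) and 79323302 (Ezh2-deficient) at day 3, 65461350 and 71953802 at day 7, and 51985214 and 57319966 at day 14. Between 17609 and 18139 genes had counts in a library. The Ezh2-deficient library was the deeper of the pair on each day, by ratios of 1.125, 1.099 and 1.103. Rn45s, the ribosomal RNA precursor, took from 1.66% to 2.98% of counts. Col2a1, the main collagen of cartilage, took 7.40% and 7.31% at day 3 and 2.04% and 1.09% at day 14 in wildtype and Ezh2-deficient libraries.

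Ezh2 (chromosome 6, 47530274 to 47595030, mm10) was lower in the Ezh2-deficient library on each day. Its levels were 24.7 against 14.7 CPM at day 3, 40.2 against 23.0 CPM at day 7 and 27.9 against 17.6 CPM at day 14. The difference shared by the 3 days was -0.74 ± 0.08 (log2, SE), with an adjusted p = 0.0729 by edgeR, which does not pass. DESeq2 gave an adjusted p = 1.83e-06 and limma-voom 0.0485, and over 16 alternatives it ranged from 1.83e-06 to 1. The deleted part of the gene was not given in the sources used here, so reads that map outside it do not check the labels. The library titles read Ezh2_cKO, a conditional knockout, and nothing measured here gives the share of cells that lost the gene. Of the other Polycomb repressive complex 2 genes, the log2 fold changes were -0.16 ± 0.09 for Ezh1, the second methyltransferase of the complex, -0.05 for Eed and -0.06 for Suz12, its core subunits. None of these passed (adjusted p = 0.483, 0.807 and 0.805), and Suz12 was 0.03 on the log2 scale without the day 14 pair.

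Across the 3 days, Sfrp5 and Nnt were lower in Ezh2-deficient than in wildtype libraries, and they were the only genes of 16280 to pass in edgeR with TMM factors and the main settings. Sfrp5 (chromosome 19, 42197971 to 42202252), a secreted inhibitor of Wnt ligands found in the surface zone of joint cartilage, was 138 against 40.5 CPM at day 3, 77.7 against 23.7 at day 7 and 21.9 against 5.66 at day 14. Its log2 fold change was -1.81 ± 0.08 (adjusted p = 0.019). Nnt (chromosome 13, 119334317 to 119409138), the mitochondrial transhydrogenase that supplies NADPH, was 57.7 against 24.0, 54.9 against 22.7 and 53.6 against 19.7 CPM, a log2 fold change of -1.33 ± 0.08 (adjusted p = 0.0424). The labels call the strain a mix, and strain and genotype cannot be told apart for Nnt, as set out under the other observations. At an unadjusted p under 0.05, 2142 genes stood apart, 1111 higher and 1031 lower. DESeq2 called 607 genes (372 higher, 235 lower) and limma-voom 40 (31 higher, 9 lower), 39 of which DESeq2 also called. Without the day 3 pair edgeR called 863 genes (383 higher, 480 lower), without the day 7 pair 0 and without the day 14 pair 0, with 829 and 1601 genes at an unadjusted p under 0.05; DESeq2 and limma-voom were not run on these subsets. Sfrp5 then had an adjusted p of 0.0023, 0.227 and 0.0692, and Nnt 0.00402, 0.398 and 0.112. Over 16 alternatives the adjusted p ranged from 1.81e-42 to 1 for Sfrp5, which passed in 11, and from 7.73e-23 to 0.757 for Nnt, which passed in 10.

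No gene passed in the upward direction in edgeR with the main settings, where 1111 were higher at an unadjusted p under 0.05, while DESeq2 called 372 and limma-voom 31. In edgeR 6 genes passed upward with RLE factors, 6 without a filter and 5 with robust dispersion. The 6 with the smallest p, which do not pass, included 3 genes of bone or mesenchyme. Bglap, which encodes osteocalcin, was 1.14 ± 0.08 higher (log2; adjusted p = 0.0559), although reads of its near-identical copies could be split with it. Tmem119, a membrane protein of osteoblasts, was 1.07 higher (adjusted p = 0.0566), and Alx1, a homeobox gene of craniofacial mesenchyme, 3.55 ± 0.27 higher (adjusted p = 0.0566). The others were Thrsp, a regulator of lipid synthesis (1.503, adjusted p = 0.0566), Epha2, an ephrin receptor (0.81, adjusted p = 0.0587), and Npnt, a matrix ligand of integrins (1.53, adjusted p = 0.0587). All 6 passed in DESeq2 (adjusted p from 4.28e-19 to 5.99e-11) and limma-voom (0.0328 to 0.041). Ibsp, the bone sialoprotein gene, was 14.4 against 56.1 CPM at day 3, 40.4 against 242 at day 7 and 8246 against 29950 at day 14 (2.13 ± 0.19, adjusted p = 0.0674; 6.52e-32 in DESeq2 and 0.0328 in limma-voom). Alpl, the alkaline phosphatase of mineralising cells, was 1.09 ± 0.17 (adjusted p = 0.111), Sp7 0.64 (0.217) and Runx2 0.25 (0.309), the last 2 being transcription factors of bone formation. Col2a1 was -0.45 ± 0.24 (adjusted p = 0.478), Acan, which encodes the proteoglycan aggrecan, -0.68 ± 0.19 (0.257), and Sox9, the chondrocyte transcription factor, -0.35 (0.308). Of the 64 genes with an adjusted p under 0.1 in edgeR, 45 were higher and 19 lower, and all 64 had the same sign on the 3 days. The test sets the difference against its spread over the days, so the choice by p itself favours a shared sign. Xist and the Y-linked genes also differed between the paired libraries. Xist, expressed from the inactive X of females, was 1065 against 842, 1130 against 677 and 1223 against 513 CPM, and the 4 Y-linked genes together were 90.8 against 122, 62.5 against 131 and 60.6 against 171 CPM.

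Other genes of the growth plate and of Polycomb control did not pass. Col10a1, the collagen of hypertrophic chondrocytes, was -0.89 ± 0.39 (adjusted p = 0.409), Mmp13, a collagenase, 0.33 (0.624), Prg4, which encodes lubricin, -0.19 (0.508), and Cdkn2a, the INK4A and ARF tumour suppressor locus and a known Polycomb target, 0.55 (0.269). Cdkn2a was 0.667 against 1.05 CPM at day 3, 7.35 against 13.02 at day 7 and 21.8 against 25.5 at day 14. Ihh, the hedgehog ligand of prehypertrophic cells, was -0.20 (0.767) and 0.07 without the day 7 pair. Spp1, which encodes osteopontin, was -0.13 (0.807) and 0.12 without the day 14 pair. Over 16 alternatives Col10a1 ranged from -1.498 to -0.4308 (adjusted p from 0.0132 to 1) and passed only without the day 3 pair, and Mmp13 ranged from 0.0001703 to 0.6934 (adjusted p from 0.318 to 1).

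**Figure D1:**
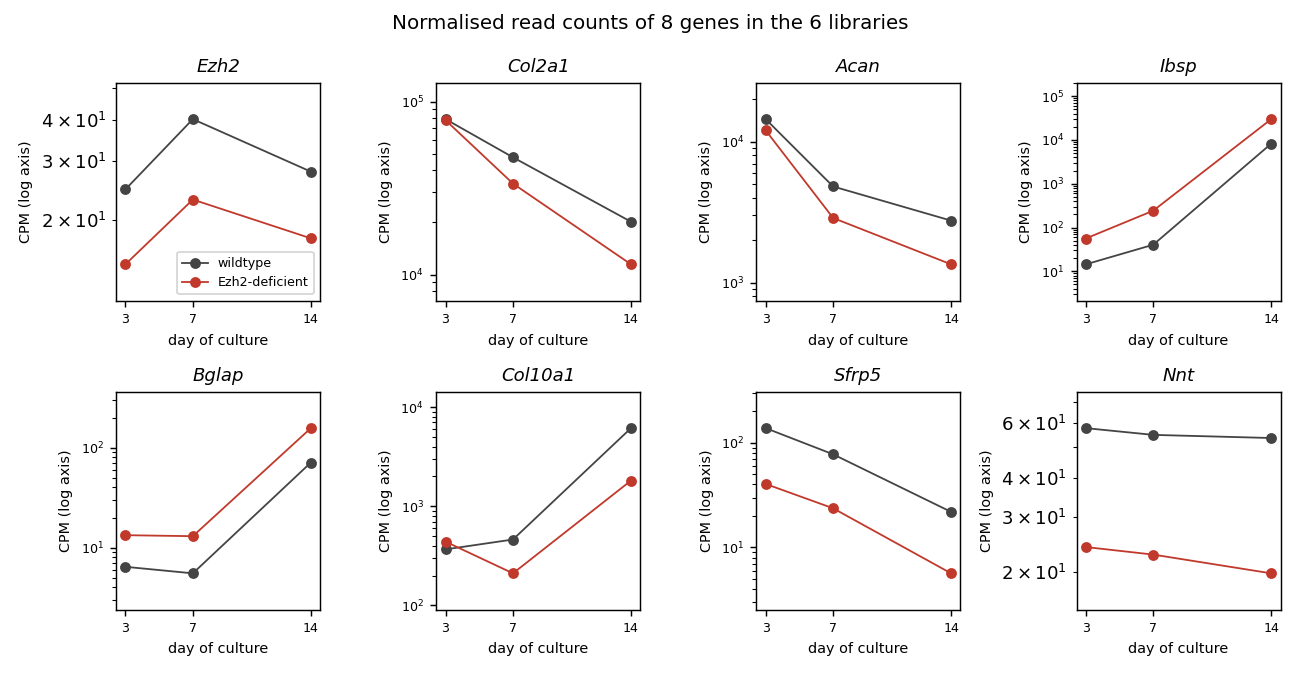
Expression in CPM (log axis) against day of culture for Ezh2, Col2a1, Acan, Ibsp, Bglap, Col10a1, Sfrp5 and Nnt, with wildtype in grey and Ezh2-deficient in red and 1 point per library. Ibsp rises from 14.4 to 8246 CPM in wildtype and from 56.1 to 29950 CPM in Ezh2-deficient libraries, and Sfrp5 and Nnt lie lower in the Ezh2-deficient library on each day.

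Of the 35 gene lists tested, camera called 18 between genotypes, 13 higher and 5 lower in Ezh2-deficient cells. The same test called 12, 8 and 8 lists in the 3 other groupings that part every day's pair and mix the genotypes. A call at the preset correlation is therefore weak evidence of a genotype difference by itself. With an estimated correlation 0 lists were called by camera, with 5 at an unadjusted p under 0.05, and fry called 6. That form of camera rests on 2 residual degrees of freedom here. For the osteoblast list the estimated correlation was -0.03, below the preset 0.01, yet its unadjusted camera p went from 4.11e-18 to 0.01. The loss of calls therefore does not by itself show that correlation between genes undoes them. Among list members only Sfrp5 passed over all genes. The osteoblast and mineralisation list was higher (31 genes, median 0.59, adjusted p = 7.19e-17; adjusted p = 0.305 with an estimated correlation). Adjusted over the list alone, 17 of its genes were higher and 3 lower in edgeR, against 0 over all genes (18 higher and 3 lower at an unadjusted p under 0.05, DESeq2 10 and 2, limma-voom 4 and 0). Ibsp, Phex (0.99, an endopeptidase of phosphate balance) and Bmp4 (1.10, a bone morphogenetic protein) were among those higher. Tnfrsf11b (-0.63), the osteoclast inhibitor osteoprotegerin, Enpp1 (-0.87), which makes the mineralisation inhibitor pyrophosphate, and Omd (-0.53), a bone proteoglycan, were lower. The hypertrophic list was higher (17 genes, median 0.20, adjusted p = 0.000391; adjusted p = 0.314 with an estimated correlation). Of its genes 4 were higher adjusted over the list alone and 0 over all genes (5 higher and 1 lower at an unadjusted p under 0.05, DESeq2 4, limma-voom 1). These were Ibsp, Alpl, Sp7 and Panx3 (0.47, a channel of maturing chondrocytes), of which all but Panx3 are also in the osteoblast list. The cartilage list was lower (30 genes, median -0.46, adjusted p = 3.95e-12; adjusted p = 0.425 with an estimated correlation). Of its genes 10 were lower adjusted over the list alone and 0 over all genes (16 at an unadjusted p under 0.05, DESeq2 12, limma-voom 0). Among these were Papss2 (-0.65), which makes the sulphate donor for proteoglycans, Clec3a (-1.27), a cartilage lectin, Matn3 (-0.88), a matrilin, and Acan. The list's median was -0.13 at day 3, -0.48 at day 7 and -0.82 at day 14. The superficial zone list was lower (12 genes, median -0.19, adjusted p = 7.26e-05; adjusted p = 0.314 with an estimated correlation), and Sfrp5 was its only member to pass, both adjusted over the list alone and over all genes.

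Lists of other cell types also stood apart. The adipocyte list was higher (10 genes, median 1.32, adjusted p = 1.47e-12; adjusted p = 0.324 with an estimated correlation). Adjusted over the list alone 9 of its genes were higher, against 0 over all genes (9 at an unadjusted p under 0.05, DESeq2 7, limma-voom 0), such as Fabp4 (1.53), a fatty acid carrier, and Plin1 (1.36), which coats lipid droplets. Its median was 2.36, 0.87 and 0.71 at days 3, 7 and 14. The smooth muscle list was higher (10 genes, median 0.72, adjusted p = 1.2e-10; adjusted p = 0.305 with an estimated correlation). Of its genes 5 were higher adjusted over the list alone and 0 over all genes (6 at an unadjusted p under 0.05, DESeq2 4, limma-voom 1). They included Myl9 (0.78) and Cnn1 (1.77), a myosin light chain and calponin. The fibroblast list was higher (24 genes, median 0.20, adjusted p = 0.00085; adjusted p = 0.425 with an estimated correlation). Of its genes 7 were higher and 1 lower adjusted over the list alone and 0 over all genes (8 higher and 2 lower at an unadjusted p under 0.05, DESeq2 5, limma-voom 0). Postn (0.89) and Tnc (0.74) were among those higher, and the small proteoglycan gene Dcn (-0.40) was lower. The tendon list was higher (7 genes, median 0.50, adjusted p = 0.0103; adjusted p = 0.324 with an estimated correlation). Adjusted over the list alone Kera (2.29), Tnmd (0.77) and Thbs2 (0.88) were higher and Fmod (-0.47) lower, against 0 over all genes (3 higher and 2 lower at an unadjusted p under 0.05, DESeq2 3 and 1, limma-voom 0). The osteoclast list was lower (9 genes, median -0.34, adjusted p = 0.00117; adjusted p = 0.324 with an estimated correlation). Only Atp6v0d2 (-1.21), a proton pump subunit, was lower adjusted over the list alone and 0 over all genes (2 at an unadjusted p under 0.05, DESeq2 1, limma-voom 0). The macrophage list was not called (17 genes, median -0.14, adjusted p = 0.223), nor were endothelium (median -0.25, 0.662), skeletal muscle (0.36, 0.246), neural cells (-0.12, 0.464) and keratinocytes (-0.30, 0.464). The erythroid list had 2 tested genes and was not tested. The sex-linked list was higher (5 genes, median 0.96, adjusted p = 0.000391; adjusted p = 0.324 with an estimated correlation). Its 4 Y-linked genes were higher and Xist (-0.78) lower adjusted over the list alone, with 0 over all genes (4 higher and 1 lower at an unadjusted p under 0.05, DESeq2 4 and 1, limma-voom 0). Without the day 3 pair the fibroblast and tendon lists were not called (adjusted p = 0.0605 and 0.128).

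The hypoxia and glycolysis list was lower in Ezh2-deficient cells (27 genes, median -0.36, adjusted p = 2.77e-18; adjusted p = 0.305 with an estimated correlation). Adjusted over the list alone 19 of its genes were lower, against 0 over all genes (20 at an unadjusted p under 0.05, DESeq2 14, limma-voom 1). These included Car9 (-0.87 ± 0.08), a carbonic anhydrase induced by hypoxia, Hk2 (-0.51) and Pfkp (-0.56), which act early in glycolysis, and Gapdh (-0.48), which has many pseudogenes. The interferon list was higher (20 genes, median 0.56, adjusted p = 5.48e-11; adjusted p = 0.437 with an estimated correlation), and all 20 fitted differences were positive. Of these, 9 were higher adjusted over the list alone and 0 over all genes (10 at an unadjusted p under 0.05, DESeq2 7, limma-voom 1), such as Isg15 (1.06), Ifit1 (0.90) and Oasl2 (0.73), antiviral effectors. The list's median was -0.04 at day 3, 0.90 at day 7 and 0.65 at day 14. The cell cycle list was lower (40 genes, median -0.53, adjusted p = 1.01e-08; adjusted p = 0.615 with an estimated correlation). None of its genes passed in edgeR, with 0 adjusted over the list alone and 0 over all genes (1 higher and 3 lower at an unadjusted p under 0.05, DESeq2 1, limma-voom 0). Its median changed sign with day, from 0.28 at day 3 to -0.65 at day 7 and -1.18 at day 14.

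Among signalling lists, Wnt was higher (29 genes, median 0.28, adjusted p = 4.47e-06; adjusted p = 0.305 with an estimated correlation). Adjusted over the list alone 6 of its genes were higher and 0 over all genes (14 higher and 1 lower at an unadjusted p under 0.05, DESeq2 6, limma-voom 0). Wnt5a (0.53) and Wnt16 (1.63) are ligands and Rspo2 (0.75) enhances the pathway, whereas Dkk1 (1.09), Dkk2 (0.83) and Sfrp2 (0.67) encode secreted inhibitors or modulators of it. The FGF and IGF list was higher (27 genes, median 0.12, adjusted p = 0.00085; adjusted p = 0.425 with an estimated correlation). Of its genes 7 were higher adjusted over the list alone and 0 over all genes (7 at an unadjusted p under 0.05, DESeq2 7, limma-voom 1), including the growth factor gene Igf1 (1.19 ± 0.13) and Igfbp3 (0.98), whose product binds it. The list of developmental regulators that Polycomb typically represses was higher (56 genes, median 0.05, adjusted p = 0.0293; adjusted p = 0.324 with an estimated correlation). Of its genes 8 were higher adjusted over the list alone and 0 over all genes (11 higher and 4 lower at an unadjusted p under 0.05, DESeq2 8 and 1, limma-voom 1). These included Alx1, Alx4 (1.51), Isl1 (1.06), Tbx2 (0.76), Tbx5 (0.66), Tbx18 (0.49) and Wnt10b (1.07), genes of limb, heart and craniofacial patterning. The inflammatory list (21 genes, median 0.27, adjusted p = 0.00397; adjusted p = 0.425 with an estimated correlation) and the unfolded protein response list (26 genes, median 0.11, adjusted p = 0.00747; adjusted p = 0.615 with an estimated correlation) were higher. In edgeR 0 of their genes passed adjusted over each list alone or over all genes (6 and 5 higher at an unadjusted p under 0.05, DESeq2 2 and 2, limma-voom 0 and 0). The developmental regulator list was not called without the day 3, day 7 or day 14 pair (adjusted p = 0.272, 0.0573 and 0.095) nor without a filter (0.252). The FGF and IGF list was not called without the day 3 pair (0.0733), nor the inflammatory and unfolded protein response lists without the day 7 pair (0.283 and 0.197).

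The remaining lists were not called. Their median log2 fold changes and adjusted p were -0.10 and 0.175 for Polycomb complex 2, 0.13 and 0.246 for Polycomb complex 1, 0.16 and 0.464 for Hox genes, -0.09 and 0.647 for matrix proteases, 0.12 and 0.104 for BMP and TGF-beta signalling, and -0.03 and 0.625 for hedgehog signalling. They were -0.03 and 0.625 for imprinted genes, 0.03 and 0.625 for oxidative phosphorylation, and 0.13 and 0.464 for immediate early genes. The sign of the median differed from that of the mean for cholesterol synthesis (-0.05 and 0.05, adjusted p = 0.461), cell cycle inhibitors (-0.15 and 0.03, 0.895) and ribosomal proteins (0.00 and -0.01, 0.677). The fry test called the osteoblast, Wnt, hypoxia, hypertrophic, developmental regulator and Polycomb complex 2 lists (adjusted p = 0.00508, 0.0112, 0.0378, 0.0378, 0.0378 and 0.0378). Leaving out a pair also added calls by camera. Without the day 14 pair the macrophage list was called lower (adjusted p = 0.00128), ribosomal proteins lower (0.025), skeletal muscle higher (0.00677) and cholesterol synthesis higher (9.71e-08). Without the day 7 pair BMP and TGF-beta signalling (0.00267) and immediate early genes (0.00228) were called higher, and without the day 3 pair imprinted genes and neural cells (0.0434 each) lower.

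**Figure D2:**
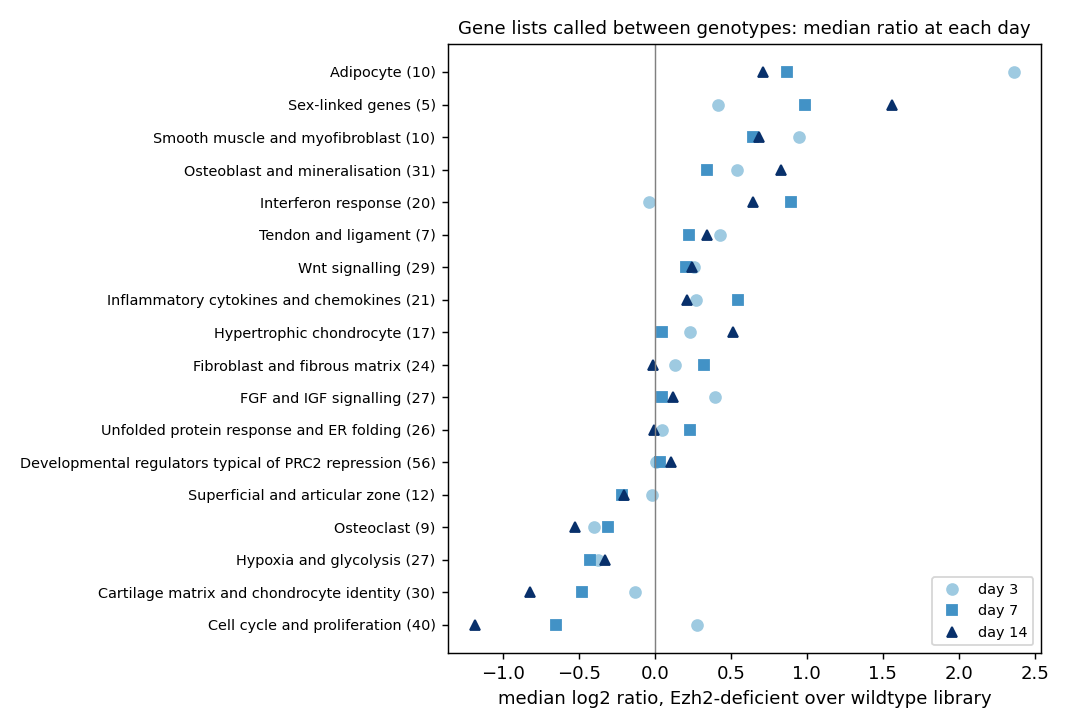
Median log2 ratio of Ezh2-deficient to wildtype at days 3, 7 and 14 for the 18 gene lists called between genotypes, 1 point per day and the number of genes in brackets. The osteoblast list lies above 0 on each day (0.54, 0.34 and 0.83), while the cell cycle list goes from 0.28 at day 3 to -1.18 at day 14.

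On single days the paired libraries could be described but not tested. At day 3, Accn1, an acid-sensing ion channel, had 0 CPM in wildtype and 107 CPM in the Ezh2-deficient library, and Car3, a carbonic anhydrase of fat and muscle, was 4.70 higher on the log2 scale (95% counting interval 4.09 to 5.57). At days 7 and 14 Tmem158, a membrane protein linked to Ras signalling, was 9.62 against 613 CPM and 6.84 against 547 CPM, log2 ratios of 5.99 (5.84 to 6.15) and 6.32 (6.11 to 6.54). By the fixed rule of size, 311 genes were at least 2-fold apart at day 3 (239 higher, 72 lower in Ezh2-deficient), 565 at day 7 (338 and 227) and 796 at day 14 (348 and 448). Across the 3 days 23 genes were higher and 10 lower on each, among them Ptprz1, a receptor phosphatase (3.14, 4.62 and 2.79), Ibsp, Bglap and Alx4 on the higher side and Nos1, Cpm and Mcoln3 on the lower. Alx1 was 3.70 higher at day 3 (3.01 to 4.68), while Corin, a serine protease (-3.92, -4.50 to -3.47), the urea transporter Slc14a1 (-3.09, -3.65 to -2.63) and Sfrp5 (-1.77, -1.86 to -1.69) were lower. At day 7 Ostn, a peptide hormone of bone and muscle (3.03, 2.80 to 3.29), and Avil, an actin-binding protein (2.86, 2.62 to 3.12), were higher, and Myrip (-2.41, -2.93 to -1.97), Mcoln3 (-2.38, -2.87 to -1.96) and Fabp7 (-1.94, -2.37 to -1.57) lower. At day 14 Ephx4, an epoxide hydrolase (5.01, 4.41 to 5.81), and Avil (3.57, 3.24 to 3.95) were higher, and Chi3l1, a secreted chitinase-like protein of chondrocytes (-2.74, -3.02 to -2.49), Mcoln3 (-2.72, -3.31 to -2.22) and Aldh3a1 (-2.71, -3.28 to -2.22) lower. These values compare the libraries and not the genotypes.

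From day 3 to day 14 genes of bone and mineralisation rose and genes of cartilage matrix fell in both genotypes. Ibsp rose by 9.12 ± 0.32 (log2, SE; adjusted p = 0.000137), Phex by 5.09 ± 0.13 (adjusted p = 0.000131) and Alpl by 4.35 ± 0.23 (adjusted p = 0.000194). Col2a1 fell by 2.37 ± 0.30 (adjusted p = 0.00262), Acan by 2.78 ± 0.24 (adjusted p = 0.000767) and Sox9 by 1.01 ± 0.14 (adjusted p = 0.00345). Macrophage genes rose too, with C1qa, a complement component made by macrophages, going from 2.03 and 1.96 CPM at day 3 to 114 and 150 CPM at day 14 in wildtype and Ezh2-deficient libraries (6.04 ± 0.16). In all, 7414 genes changed, 3769 up and 3645 down, of which 2414 and 1306 were at least 2-fold apart. Leaving out 1 library at a time gave between 4912 and 6605 genes, and the count of 4912 was without the Ezh2-deficient day 14 library. Mepe, a matrix protein of osteocytes, and Nell1, a secreted osteogenic protein, had 0 counts at day 3. Against a floor of 3 fragments per library, Mepe was at least 21.7-fold higher in wildtype and at least 134-fold higher in Ezh2-deficient cells at day 14, and Nell1 at least 17.1-fold and 59.7-fold higher.

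The osteoblast list rose (31 genes, 24 up and 2 down, the same adjusted over the list alone; median 3.16, adjusted p = 6.5e-26; adjusted p = 0.228 with an estimated correlation). Dmp1, an osteocyte matrix protein, rose by 8.23 ± 0.65 and Ifitm5, a membrane protein of mineralising osteoblasts, by 7.27 ± 0.28. Atf4, the stress transcription factor, and Slc20a2, a phosphate transporter, fell by 1.47 and 0.98. The hypertrophic list rose (17 genes, 14 up and 1 down, the same adjusted over the list alone; median 2.23, adjusted p = 7.36e-12; adjusted p = 0.293 with an estimated correlation). Col10a1 rose by 3.01 ± 0.50 (adjusted p = 0.00616), Ihh by 2.81 ± 0.31 and Mmp13 by 2.31 ± 0.33, and Pcdh8 (-4.38), a protocadherin, fell. Runx2, Sp7 and Spp1 rose by 1.85, 3.14 and 3.16. The cartilage list fell (30 genes, 2 up and 28 down, the same adjusted over the list alone; median -2.09, adjusted p = 2.26e-15; adjusted p = 0.454 with an estimated correlation). Papss2 fell by 3.21, Fgfr3, a receptor that restrains chondrocyte growth, by 2.18, and Sox6, a partner of Sox9, by 1.46, while the matrix genes Matn4 (1.22) and Chad (2.96) rose. Prg4 fell by 0.63 ± 0.14 (adjusted p = 0.0146), a call that was lost without the wildtype day 3 library (0.0514) or the wildtype day 14 library (0.101) and ranged from 0.00314 to 0.101 over 17 alternatives. Car9 rose by 3.34, and Ezh2 did not pass (0.22, adjusted p = 0.129).

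The macrophage list rose (17 genes, 16 up, the same adjusted over the list alone; median 3.86, adjusted p = 2.03e-42; adjusted p = 0.372 with an estimated correlation). C1qb rose by 5.47 and Emr1, the F4/80 antigen, by 4.08. The interferon list rose (20 genes, 19 up, the same adjusted over the list alone; median 2.69, adjusted p = 3.77e-13; adjusted p = 0.454 with an estimated correlation). Oasl2 rose by 3.98 and the RNA sensor Ifih1 by 2.94. The fibroblast list rose (24 genes, 15 up and 1 down, 16 and 1 adjusted over the list alone; median 1.53, adjusted p = 1.76e-12; adjusted p = 0.372 with an estimated correlation). Postn rose by 3.70 and Fap, a protease of activated fibroblasts, by 2.501. Smaller shifts were seen in smooth muscle (10 genes, 5 up, the same adjusted over the list alone; median 0.81, adjusted p = 0.0483; adjusted p = 0.454 with an estimated correlation) and tendon (7 genes, 6 up, the same adjusted over the list alone; median 1.43, adjusted p = 0.0175; adjusted p = 0.454 with an estimated correlation). Myl9 rose by 1.67 and Tnmd, a tendon membrane protein, by 2.27. The protease list rose (16 genes, 10 up and 2 down, the same adjusted over the list alone; median 1.53, adjusted p = 0.0022; adjusted p = 0.454 with an estimated correlation). Its members that rose included both the collagenase Mmp13 and the inhibitor Timp1 (2.29), while Mmp9 (-2.84) and Timp3 (-1.53) fell. The inflammatory list rose (21 genes, 10 up and 1 down, the same adjusted over the list alone; median 1.35, adjusted p = 0.0316; adjusted p = 0.454 with an estimated correlation). The chemokine gene Cxcl12 rose by 3.49 and Lcn2 (-4.26), an iron-siderophore carrier, fell. The smooth muscle list was not called without the wildtype day 3 (adjusted p = 0.084), wildtype day 7 (0.0647), Ezh2-deficient day 7 (0.0716) or wildtype day 14 library (0.0935), nor the inflammatory list without the wildtype day 14 library (0.125).

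Of 4 signalling lists 3 rose, and BMP and TGF-beta signalling was not called (median 0.28, adjusted p = 0.28). The Wnt list rose (29 genes, 17 up and 5 down, the same adjusted over the list alone; median 0.67, adjusted p = 0.00176; adjusted p = 0.372 with an estimated correlation). Its largest rises included the inhibitor genes Dkk1 (5.27) and Sfrp2 (3.95), and the target gene Nkd1 (-3.38) fell. The hedgehog list rose (11 genes, 6 up and 2 down, the same adjusted over the list alone; median 1.63, adjusted p = 0.00114; adjusted p = 0.372 with an estimated correlation; adjusted p = 0.0629 without a filter). Hhip, Gli1 and Ptch1, targets of the pathway, rose by 4.36, 1.63 and 1.70, and Pthlh (-2.86), the gene of parathyroid hormone-related protein, fell. The FGF and IGF list rose (27 genes, 18 up and 5 down, the same adjusted over the list alone; median 1.36, adjusted p = 0.00774; adjusted p = 0.454 with an estimated correlation). Igf1 rose by 4.99 ± 0.18, and Igf2, an imprinted fetal growth factor gene, fell by 3.43 ± 0.19. The imprinted list fell (21 genes, 2 up and 17 down, the same adjusted over the list alone; median -1.61, adjusted p = 2.97e-11; adjusted p = 0.454 with an estimated correlation). Dlk1 (-4.35) and Peg3 (-2.66) fell, while Mest (1.07) and Slc38a4 (1.03) rose. Cdkn2a and its neighbour Cdkn2b, inhibitors of the cell cycle, rose by 4.81 ± 0.22 and 2.36.

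Lists of protein and lipid synthesis fell. All 48 ribosomal protein genes fell, over all genes and adjusted over the list alone (median -0.91, adjusted p = 3.96e-12; adjusted p = 0.494 with an estimated correlation). Examples were Rplp1 (-1.19) and Rpl22 (-1.05), and most have pseudogenes that could share their reads. The unfolded protein response list fell (26 genes, 15 down, 18 adjusted over the list alone; median -0.40, adjusted p = 0.00062; adjusted p = 0.454 with an estimated correlation). The stress genes Ddit3 (-2.68) and Trib3 (-2.89) fell. The cholesterol list fell (22 genes, 9 down, 13 adjusted over the list alone; median -0.78, adjusted p = 0.00304; adjusted p = 0.6 with an estimated correlation). Srebf1 (-2.02), its transcription factor, fell. Oxidative phosphorylation genes fell slightly (38 genes, 14 down, 13 adjusted over the list alone; median -0.22, adjusted p = 0.0175; adjusted p = 0.454 with an estimated correlation). Camera with an estimated correlation called 0 of the 35 lists (3 at an unadjusted p under 0.05), and fry called 25. The adipocyte list was not called (median 1.39, adjusted p = 0.0578), but it was when any library except wildtype day 14 was left out (adjusted p from 3.09e-06 to 0.0414). Single genes with the largest falls were Otog, an inner ear matrix protein (-7.74 ± 0.51), the cation channel gene Trpm5 (-6.87), the transporter genes Slc22a14 (-6.52) and Slc2a5 (-6.45), and the imprinted gene Magel2 (-6.28). Among the largest rises were Ptprz1 (6.92) and Col13a1, a transmembrane collagen (6.57).

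**Figure D3:**
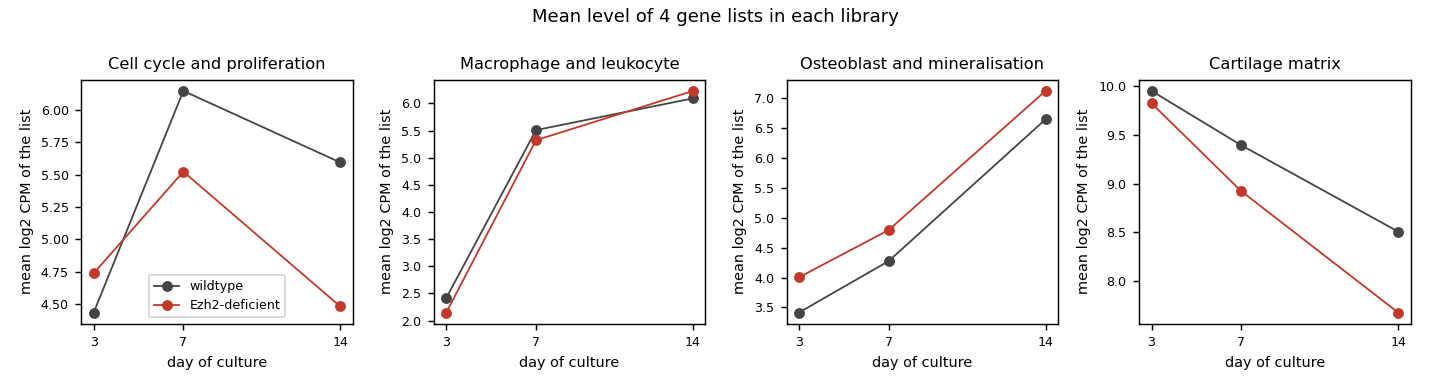
Mean log2 CPM of the cell cycle, macrophage, osteoblast and cartilage lists in each library against day of culture, wildtype in grey and Ezh2-deficient in red, 1 point per library. The macrophage mean goes from 2.42 to 6.09 in wildtype and from 2.15 to 6.23 in Ezh2-deficient libraries, and the cartilage mean falls from 9.95 to 8.51 and from 9.82 to 7.68.

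Macrophage, interferon and adipocyte genes rose mainly between days 3 and 7, and bone genes mainly between days 7 and 14. The median of the macrophage list was 3.20 from day 3 to day 7 and 0.73 from day 7 to day 14, that of the interferon list 3.27 and -0.64, that of the adipocyte list 2.87 and -1.19, and that of the osteoblast list 0.72 and 2.37. From day 3 to day 7, 16 of 17 macrophage genes rose, the same adjusted over the list alone (adjusted p = 1.17e-43; adjusted p = 0.417 with an estimated correlation). Of 20 interferon genes 19 rose, the same adjusted over the list alone (adjusted p = 5.58e-28; adjusted p = 0.417 with an estimated correlation). From day 3 to day 7 the interferon-induced GTPase genes Ifi47 and Iigp1 rose by 5.38 ± 0.27 (adjusted p = 0.000407) and 5.26 ± 0.19 (adjusted p = 0.000334), and Egfl6, a secreted growth factor-like protein, by 5.14 ± 0.55 (adjusted p = 0.00228). Otog fell by 5.73 ± 0.44 (adjusted p = 0.000854), the aldo-keto reductase gene Akr1b7 by 5.11 ± 0.65, Fibcd1, a chitin-binding receptor, by 4.87 ± 0.75 and the ion channel gene Accn4 by 4.78 ± 0.44. In all 10 adipocyte genes a rise passed, over all genes and adjusted over the list alone (adjusted p = 4.7e-06; adjusted p = 0.417 with an estimated correlation). Avil fell by 4.75 ± 0.97 (adjusted p = 0.0162), a call lost without the wildtype day 7 library (0.126), without the Ezh2-deficient day 7 library (0.072) and without a genotype term (0.0766), with a range of 8.43e-06 to 0.126 over 17 alternatives. In all 5881 genes changed, 3172 up and 2709 down. Without the wildtype day 7 library 1860 genes were called and without the Ezh2-deficient day 7 library 1977, while the other libraries left out in turn gave up to 5699. Scaled by total counts alone the split was 4316 up and 1250 down, and the median of all genes was then 0.189, against -0.0211 with TMM.

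From day 7 to day 14, Ibsp rose by 7.30 ± 0.30 (adjusted p = 0.0021) and Ptprz1 by 6.89 ± 0.40 (adjusted p = 0.00386). The osteoblast list rose with 20 of 31 genes up, 22 adjusted over the list alone (adjusted p = 5.39e-74; adjusted p = 0.077 with an estimated correlation). Lipc, a lipase, went from 0.0851 and 0.203 CPM to 7.07 and 54.8 CPM, and Gal, a neuropeptide, from 0 and 0.0254 to 2.51 and 22.1 CPM. Lhcgr, a gonadotropin receptor gene, fell by 4.24 ± 0.39 (adjusted p = 0.00899) and Magel2 fell by 3.59 ± 0.22 (adjusted p = 0.00429). Camp, an antimicrobial peptide, fell by 3.54 ± 0.51 (adjusted p = 0.0224), Ucma, a secreted cartilage protein, fell by 3.53 ± 0.47 (adjusted p = 0.0181) and Trpm5 fell by 3.32 ± 0.62 (adjusted p = 0.0441). In all 922 genes changed, 550 up and 372 down, and 383 up and 482 down with total counts alone, where the median of all genes was -0.156, against -0.0163 with TMM. Without the wildtype day 3 library 2506 genes were called, without the Ezh2-deficient day 3 library 2526, without the wildtype day 7 library 101, without the Ezh2-deficient day 7 library 45 and without the Ezh2-deficient day 14 library 157. DESeq2 called 1895 and a model without genotype 257. Gal, the osteocyte gene Sost, Lhcgr, Camp, Ucma and Trpm5 lost their calls when either day 7 library was left out. Without the wildtype day 7 library their adjusted p were 0.0606, 0.0611, 0.0769, 0.14, 0.0837 and 0.165, and without the Ezh2-deficient day 7 library 0.139, 0.115, 0.0873, 0.193, 0.134 and 0.263. Without the Ezh2-deficient day 14 library Lipc (0.0541), Gal (0.0899), Sost (0.0801), Lhcgr (0.0588), Camp (0.122) and Trpm5 (0.0687) did not pass, and Ibsp (0.0682) and Ptprz1 (0.135) did not in the model without genotype. In the model without genotype Gal (adjusted p = 0.0523), Lipc (0.0569), Sost (0.0514), Camp (0.0523), Ucma (0.136) and Trpm5 (0.0806) did not pass either. Of the 10 genes named for this comparison only Magel2 passed in all 17 alternatives, with an adjusted p up to 0.0336.

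The genotype difference itself changed with day for genes of cell division. Mki67, the proliferation marker, had log2 ratios of Ezh2-deficient to wildtype of 0.36 at day 3, -0.60 at day 7 and -1.31 at day 14, and the mitotic cyclin gene Ccnb1 0.50, -0.71 and -1.70. Per doubling of day the ratio fell by 0.75 ± 0.07 for Mki67, 0.99 ± 0.07 for Ccnb1, 0.94 ± 0.08 for Cenpf, a kinetochore protein, and 0.74 ± 0.07 for Top2a, a DNA topoisomerase. Col10a1 fell in the same way, with ratios of 0.26, -1.13 and -1.76 (-0.92 ± 0.11; adjusted p = 0.044). The test called 100 genes, 10 with a ratio rising and 90 with a ratio falling with day. Of the 40 cell cycle genes 22 fell over all genes and 39 adjusted over the list alone (camera adjusted p = 1.78e-83; adjusted p = 0.864 with an estimated correlation). These 22 were more than their share of the falling genes (Fisher's exact test, adjusted p = 5.08e-39). Fisher's test counts genes as independent. In the genotype fit the estimated correlation was 0.98 for this list and 0.73 for the cholesterol list. With 1 library per genotype and day, its p for either list does not measure evidence from separate cultures. Of the 22 cholesterol genes 4 fell, among them Sc4mol and Nsdhl, enzymes of the pathway, and its regulator Insig1, and 16 fell adjusted over the list alone (adjusted p = 1.36e-21; adjusted p = 0.864 with an estimated correlation; Fisher's exact test, adjusted p = 0.000107). In the cartilage list Matn1 (-1.12) and Cytl1 (-0.82) fell, and 14 fell and 1 rose adjusted over the list alone (adjusted p = 1.42e-13; adjusted p = 0.864 with an estimated correlation). The ribosomal list shifted upward (median 0.18, adjusted p = 1.12e-09; adjusted p = 0.864 with an estimated correlation) with 0 of its genes called in edgeR over all genes or adjusted over the list alone. Among other cell types the adipocyte list shifted downward (median -0.69, adjusted p = 5.09e-08; adjusted p = 0.864 with an estimated correlation; 6 genes adjusted over the list alone and 0 over all genes) and the macrophage list upward (median 0.13, adjusted p = 0.000869; adjusted p = 0.864 with an estimated correlation). Camera also called smooth muscle (adjusted p = 0.00162), neural cells (0.0268), FGF and IGF signalling (0.00869) and imprinted genes (0.00067) downward, and interferon (1.76e-06) and sex-linked genes (0.000166) upward. With an estimated correlation the adjusted p was 0.864 for each of these except interferon (0.884). Over all genes 1 gene each passed in the smooth muscle, neural and interferon lists (Tagln, S100b and Ifi44, the first 2 named after their values were seen), and adjusted over the list alone 3, 1 and 1. Xist and the Y-linked genes moved over the same days, the Y-linked median ratio being 0.44, 1.11 and 1.59 and that of Xist -0.34, -0.74 and -1.25.

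Among the named genes the ratio rose most for Avil (1.78 ± 0.22 per doubling of day, adjusted p = 0.0466), the carbonic anhydrase gene Car6 (1.44 ± 0.10) and Sspo, a secreted glycoprotein of brain fluid (1.47 ± 0.15). It also rose for the protease inhibitor gene Slpi (1.30 ± 0.16) and Pappa2, a protease of IGF-binding proteins (1.19 ± 0.13). It fell most for the xenobiotic enzyme gene Cyp1a1 (-2.77 ± 0.34, adjusted p = 0.046), the glycosyltransferase gene Galnt13 (-1.77 ± 0.16), C1ql3 (-1.57), the homeobox gene Lhx9 (-1.48) and Hsd11b1, which regenerates active glucocorticoid (-1.31). Cyp1a1 was 1.63 against 0.0365 CPM at day 14. The Ezh2-deficient value was 1 fragment, under the floor of 3 fragments (0.109 CPM), so the size of this slope is uncertain. The interferon gene Ifi44 (0.95) and the superficial zone gene Vit (0.64) also rose. With a filter of 1 CPM in 3 libraries or with day on a linear scale edgeR called 0 genes, although 1879 and 1934 had an unadjusted p under 0.05, and DESeq2 called 336 under the main settings. The named genes then lost their calls. Over 11 alternatives the adjusted p ranged from 9.62e-07 to 0.12 for Mki67, which passed in 9, and from 0.0131 to 0.179 for Avil, which passed in 7. With total counts alone 270 genes were called (20 rising, 250 falling) and without a filter 247 (27 and 220). With 1 residual degree of freedom no day could be left out of this test.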

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

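The tests of library depth and of sex make-up for the cell cycle genes were chosen after the results were seen, and that of depth replaced a first one by thinning, which could hardly move such a list. The results here are those in which the genotype difference changed between days, by a test of that change per doubling of day in edgeR. That test called 100 genes, 10 with a rising and 90 with a falling ratio of Ezh2-deficient to wildtype. The ratio rose by 1.776 per doubling of day for Avil, 1.473 for Sspo, 1.44 for Car6, 1.302 for Slpi and 1.186 for Pappa2. The slope was -2.768 for Cyp1a1, -1.77 for Galnt13, -1.571 for C1ql3, -1.484 for Lhx9 and -1.314 for Hsd11b1. It was -0.9872 for Ccnb1, -0.7524 for Mki67, -0.7434 for Top2a, -0.9409 for Cenpf and -0.9152 for Col10a1, and Col10a1 was added to the named genes of this test after it was seen to pass. Cyp1a1 had 1 fragment in the Ezh2-deficient day 14 library, under the floor of 3 fragments, so the size of its slope is uncertain.

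The cell cycle genes made the largest group among the fixed lists, with a ratio above 0 in 40 of 40 at day 3 and below 0 in 39 of 40 at days 7 and 14. A difference in depth is argued against, since the log2 depth ratio of the paired libraries changed by only -0.01376 per doubling of day, against a median of -0.69 for the list (central 95% of its genes -0.94 to -0.29). A mix of sexes stays open: in proportion to the Y-linked genes the day 3 median would have been -0.32, against 0.28 measured (a gap at the 100th percentile of random lists), but this rests on 1 pair of libraries and an assumed proportion, and the list fell over the days in which the Y-linked ratio rose. Other differences between the cultures, such as density or handling, stay open too. The CPM sum of the list was 1445, 2566 and 1409 at days 3, 7 and 14 in Ezh2-deficient libraries, against 1143, 3733 and 2701 in wildtype, so less proliferation than in wildtype at days 7 and 14, with a smaller rise at day 7 and none left at day 14, is a hypothesis that these libraries may reflect.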

How the results depend on the processing

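The genotype difference rested on few calls, and relative to its size its count moved with the processing more than those of the day comparisons. From 2 genes (0 higher, 2 lower) it went to 9 with RLE factors (6 and 3), 9 without a filter (6 and 3), 8 with robust dispersion (5 and 3) and 1 with a filter of 1 CPM in 3 libraries (0 and 1). It was 607 with DESeq2 and 40 with limma-voom. In edgeR it was 0 with total counts only, 0 without a day term and 0 with log2 day as a linear term, where 2042, 212 and 840 genes had an unadjusted p under 0.05; the other tools were not run with these settings. Leaving out each day's pair gave 0 to 863 genes, where fewer samples were fitted. For day 14 against day 3, leaving out 1 library gave 4912 to 6605 genes, for day 7 against day 3 1860 to 5699, and for day 14 against day 7 45 to 2526. The last was 1895 with DESeq2 and 257 without a genotype term. For the trend with day the count was 270 with total counts only, 247 without a filter, 336 with DESeq2, 0 with a filter of 1 CPM in 3 libraries and 0 with day on a linear scale, the last 2 in edgeR with 1879 and 1934 genes at an unadjusted p under 0.05. On single days a minimum of 5 CPM left 110, 280 and 458 genes at days 3, 7 and 14, and no minimum gave 622 and 926 at days 3 and 7. With an estimated correlation camera called 0 lists between genotypes and 0 between days 14 and 3, with 5 and 3 at an unadjusted p under 0.05. That form rests on 2 residual degrees of freedom in these fits, which limits what can pass. The fry test called 6 lists between genotypes and 25 between days. At day 14 total counts alone gave 291 higher and 531 lower, against 348 and 448. Where the construction of an alternative does not show it, the cause was not tested.

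Directions of the named genes held better than their calls. These genes were chosen from the same 6 libraries that the alternatives refit in whole or in part, so a kept sign is weak evidence. Of all 16280 tested genes, 36.3% had the same sign on the 3 days. Of 828 values of 52 named genes for the genotype difference under alternatives, 706 kept their direction and side of the threshold, 107 newly passed, 11 lost their call and 4 changed sign. The 4 were Ihh, 0.002911 with log2 day as a linear term and -0.5347 to 0.07417 over left-out days (highest without day 7), and, both highest without day 14, Spp1 (-0.2977 to 0.1177) and Suz12 (-0.1479 to 0.02788). These did not pass either way. For day 14 against day 3, 862 of 864 values kept both, for day 7 against day 3 148 of 151, for day 14 against day 7 139 of 167 and for the trend 124 of 165. Of the 18 lists called between genotypes 14, 15 and 17 were called in the same direction without the day 3, 7 and 14 pair, and 18 with RLE factors. The genotype test compared libraries paired by day. Beyond that no paired analysis was possible because the labels carry no replicate numbers. Leaving out a library was not run for the trend with day, since no residual degree of freedom would remain. Halved counts and leaving out Rn45s were chosen after seeing the data. Depth limits values under about 0.114 CPM, the highest floor of 3 fragments.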

Other observations

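Of the tests in this part, those of sex make-up, of strain sequence carried with the Ezh2 allele and of a lower share of chondrocytes were chosen or changed after results were seen. The genes in this and the next paragraph were singled out after their values were seen. The 4 stress genes Trib3, Asns, Chac1 and Ddit3 were higher in Ezh2-deficient libraries at days 7 and 14. Trib3, a pseudokinase, was 314 against 310 CPM at day 3, 18.3 against 82.3 at day 7 and 22.1 against 96.6 at day 14 in wildtype and Ezh2-deficient libraries. Asns, asparagine synthetase, was 378 against 403, 51.5 against 153 and 56.5 against 162 CPM. Chac1, which degrades glutathione, had log2 ratios of -0.56, 2.10 and 1.76, and Ddit3, a stress transcription factor, -0.25, 1.51 and 0.69. None of these passed the trend test in edgeR, and the unfolded protein response list had medians of 0.05, 0.23 and -0.01.

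Some genes expressed in both genotypes at day 3 were lower in wildtype than in Ezh2-deficient libraries at day 14, although Avil and Car6 fell in both. Tmem158 was 661 and 397 CPM at day 3, then 9.62 against 613 at day 7 and 6.84 against 547 at day 14. Avil was 270 and 242 CPM at day 3, then 4.31 against 31.4 and 2.74 against 32.8, and Car6 60.5 and 59.0, then 3.12 against 10.8 and 0.722 against 6.31. Ephx4 was 16.1 and 22.3 CPM at day 3, 0.908 and 0.636 at day 7 and 0.722 against 24.2 at day 14. Accn1 was seen at 107 CPM in the Ezh2-deficient day 3 library alone, and at up to 0.114 CPM in the other 5. It was not among the genes tested. Fat-associated genes were apart at day 3, with Car3 at 0.516 against 14.2 CPM and Cfd, the adipokine adipsin, at 0.0607 against 1.91 CPM, and at day 14 at 15.9 against 26.8 and 10.0 against 13.8 CPM.

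Nnt was lower in the Ezh2-deficient library on each of the 3 days by nearly the same ratio. Nnt lies on chromosome 13 and Ezh2 on chromosome 6, so strain sequence linked to the Ezh2 allele is excluded, and the slope per doubling of day, -0.07554 (2 SE bounds -0.22 to 0.07), lies apart from the -0.66 that a mix of sexes would need over the 3 days if Nnt moved in proportion to the Y-linked genes. That test replaced a first one, which set a counting interval against the same prediction. A known deletion in Nnt is carried by the substrain C57BL/6J, and the labels call the strain a mix, so a segment of another strain around Nnt may account for the level. The 17 other genes within 5 Mb had a median absolute log2 fold change of 0.13, at the 61.03 percentile of random lists, and since strains can differ at Nnt alone this decides nothing, so strain and genotype cannot be told apart for Nnt here.

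Camera at the preset correlation called osteoblast genes higher and cartilage genes lower in Ezh2-deficient libraries (adjusted p = 0.305 and 0.425 with an estimated correlation), with 8 of 31 and 5 of 30 genes of opposite sign. A mix of sexes stays open for both: the day 3 medians were 0.54 and -0.13, against 0.23 and -0.22 in proportion to the Y-linked genes (gaps at the 100th and the 99.48 percentile of random lists), but this rests on 1 pair of libraries and an assumed proportion. A lower share of chondrocytes would raise all other cell types alike. The adipocyte list lay 1.46 above the macrophage list in mean log2 fold change (27 genes, permutation p = 1e-05, the smallest that 100000 permutations can give). The adipocyte list had the highest median of the cell type lists compared, so its choice favoured a small p. Medians across the days were -0.14 for macrophage, -0.25 for endothelium, -0.34 for osteoclast and 0.36 for skeletal muscle genes. The macrophage median was -0.23, -0.23 and 0.13 at days 3, 7 and 14. These values argue against an even rise in these libraries. The permutation counts genes that move together as independent, with 1 library per genotype and day. Its p therefore does not measure the spread between cultures. A change in the share of a single cell type stays open. Ezh2-deficient cultures being further along the course from day 7 to day 14 is a candidate explanation for the osteoblast list: of the 550 genes that rose over those days 66.5%, 64.5% and 79.1% were higher, and of the 372 that fell 58.06%, 59.4% and 70.7% were lower in the Ezh2-deficient library at days 3, 7 and 14, against 50.1%, 49.3% and 49.9% of all genes higher. All 6 libraries entered the choice of these genes, and a later stage does not account for every list: the hypoxia list was positive in 26 of 27 genes from day 7 to day 14 yet lower in Ezh2-deficient libraries (medians -0.37, -0.43 and -0.33), and the adipocyte list was negative in 10 of 10 yet higher (2.36, 0.87 and 0.71).

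Among the 10 splits of the 6 libraries into 3 and 3, the real one gave 2 genes and the highest other 1, and the real one gave 18 lists and the highest other 16. With day as a factor, a split that does not part every day's pair compares the genotypes within 1 day only. The highest other values came from such splits, so they do not show what a grouping without a genotype difference would give. Even with 10 splits no share under 0.05 can be reached. The 3 other splits that part every day's pair gave 0, 0 and 0 genes in edgeR, with 381, 113 and 1013 at an unadjusted p under 0.05 against 2142 in the real split, and 12, 8 and 8 lists; DESeq2 and limma-voom were not run on them. Genes within 10 Mb of Ezh2 (113 genes) had a median absolute log2 fold change of 0.15, at the 85.66 percentile of random lists.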
